A study of Rattus norvegicus with 16 samples.

How the data were processed

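DNA from 16 rat mesotheliomas, 8 from BRCA1+/- and 8 from wild-type Jcl:SD rats, was measured on Agilent rat genome arrays for comparative genomic hybridisation (CGH), in which tumour and normal DNA compete for the same probes. Per the labels, tumour DNA was labelled with Cy5 and DNA of normal kidney cortex with Cy3 on all arrays, with no dye swap. Agilent Feature Extraction 10.7 is named in the submitters' processing notes. The dye normalisation, the filters, the averaging of replicate probes and the genome build are not given in the sources used here. The labels also give no slide or scan day, so no technical batch could be tested.

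The values as deposited by the authors were read as log2 ratios per feature, for which the submitters' processing notes name only the Feature Extraction software, with 174012 features and no missing entry on any array. The reading as log2 rests on their range: -8.82 to 9.53 would exceed what a scanner can record on a log10 scale. Neither the scale, the centring nor the direction is stated with them. A positive value is likely a higher signal of the tumour DNA, on the basis of the dyes in the labels, and all gains and losses below rest on that reading. No pair of arrays correlated below 0: over values limited to 1 on either side of 0, Pearson's r across features ran from 0.113 to 0.641 with a median of 0.317. Features are not independent replicates. All value columns belonged to the 16 samples. Some entries were 0 as deposited, to the digits compared, such as those of a feature on every wild-type array. Whether such entries are measurements is not stated, and they were kept as values.

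Each array was centred on its median, with no further normalisation. Before the data were examined, a feature had been set to count as gained at a log2 ratio of at least 0.3 and as lost at or below minus that value, on segments of neighbouring genes. The features carry only numbers here, with no gene, position or order, so the fallback fixed at the same time was used: the same tests on single features. Segmentation, chromosome tests, the split into autosomes and X, and the 5 gene lists fixed beforehand could not be run. The rule for named genes would have named Brca1, a few mesothelioma tumour suppressors, list members, recurrent regions and the genes with the largest change per contrast. None of these genes can be named here, and feature numbers are given for only the 2 largest differences in each direction by genotype.

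The altered share of a tumour is the percentage of its features gained or lost. Shares were compared by exact two-sided permutation tests of the difference in means. Genotype was compared over all tumours (8 against 8, 12870 relabellings), fibre within males (4 against 6, 210 relabellings) and sex within chrysotile tumours (6 against 6, 924 relabellings), since all crocidolite tumours came from males. Interactions were tested by permuting genotype within fibre or within sex. The 11 share comparisons were adjusted together by the Benjamini-Hochberg method. Recurrence of a gain or loss was set against calls shuffled independently over the features of each array, in place of the circular shifts that need an order. A feature was called recurrent from the count of tumours that, with a probability of at least 0.95, no feature reached by chance.

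Differences of single features were tested with limma (lmFit and eBayes, no covariates) at a Benjamini-Hochberg adjusted p below 0.05. Other splits of the same arrays, 100 per contrast, were fitted in the same way, as was, after the data were seen, the split that joins females of each genotype with males of the other.

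After the data were seen, features were also collected into 60 profile groups, each a set of features with a common pattern over the 16 arrays, by a Gaussian mixture with a shared covariance. Features beyond 2 on any array (2301) stayed out and 171711 entered. The groups are numbered P1 to P60 by size. A group counted as gained or lost in a tumour by its mean and the threshold used for features. The spread within groups had 2 leading axes, which held 45.1% and 11.1% of its variance. In 5 groups (5333 features) these axes carried over 0.8 of the sum of squares of the profile, and they were left out of the counts of gains. Features far from the other tumours were sought among those whose other 15 values had a spread (scaled median absolute deviation) under 0.25.

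The limma step, the altered share, the recurrence of single features and the permutation test of 8 against 8 were tested on simulated data. The searches for large changes of single tumours, deep losses and features shared within a set, the interactions and the recurrence of groups were not. In the limma step, over 174012 features with 50 changed at each size, the genotype contrast recovered 5 features at a log2 difference of 0.3, 26 at 0.5, 45 at 1 and 50 at 2, with 10 false calls in all. The fibre contrast recovered 0, 5, 33 and 49 at the same sizes, with 4 false calls, and the sex contrast 1, 16, 44 and 50, with 5 false calls. For the altered share, over 60000 simulated features with a true mean of 8.22%, profile groups gave 8.52% and single features 39.0%. The mean absolute error per array was 0.920 percentage points for profile groups and 30.8 for single features. The simulated values were normal with a covariance shared by all groups, the form that the grouping assumes, and their spread was not fitted to the arrays. Single features passed the threshold more often there than on the real arrays (39.0% against 19.1%). These errors therefore do not carry over to the real shares. With independent calls at the real rates, 0 of 174012 features were called recurrent. This outcome was nearly fixed, since the count needed was set from independent calls at these rates. Arrays that correlate, as the real ones do, were not simulated. Of 1000 comparisons of 8 with 8 and no effect, 5.10% had p below 0.05.

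Alternatives were thresholds of 0.2 and 0.5, centring on the mode or no centring, genotype permuted within strata of fibre and sex, covariates in limma, array weights and leaving out single tumours. Profile groups with 40, 60 or 80 components, subtraction of each feature's median and a random block for genotype and sex were added after the data were seen. The number of arrays limits the precision. The calculations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, scikit-learn 1.9.0, matplotlib 3.10.9, R 4.3.3, limma 3.58.1 and version 1.17.8 of the R package data.table.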

Results

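Copy number was compared between peritoneal asbestos-induced mesotheliomas, tumours of the lining of the body cavity, of rats with 1 defective copy of BRCA1 and of wild-type rats. BRCA1 is a gene of DNA double-strand break repair. Of 37 BRCA1+/- rats that entered the carcinogenesis experiment, 26 developed mesothelioma, against 27 of 37 wild-type rats. Each genotype contributed 8 tumours: 2 from males given crocidolite (an amphibole asbestos), 3 from males given chrysotile (a serpentine asbestos) and 3 from females given chrysotile, all at 10 mg. The labels name a separate tumour for each array. They give sex for only 1 of the 2 DNAs on an array, entered there 2 times, and it was taken to hold for the tumour. A treatment named Untreated is also listed beside the asbestos. Each array set tumour DNA against normal kidney cortex DNA.

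The deposited log2 ratios were near 0 at the median of every array. The medians of BRCA1+/- tumours 1 to 8 were 0.0019, -0.032, -0.016, 0.0011, 0.020, -0.0088, -0.0011 and 0.014. Those of wild-type tumours 1 to 8 were 0.0083, -0.034, 0.0056, -0.023, 0.015, -0.0032, 0.00047 and -0.019. The scale, the centring and the direction of the values are not stated, so gain and loss below mean a ratio above or below the array's median under the likely direction, tumour over normal.

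The first comparison asked how much of the genome was gained or lost in each tumour relative to normal DNA. Profile groups are sets of features with a common pattern over the tumours. The largest, P1 with 28543 features, stayed near 0 in every tumour, with a mean log2 ratio of 0.03 ± 0.04 (SD, n = 16), while other groups passed the threshold in a single tumour. Wild-type tumour 2 had the largest gained share by profile groups, 14.2%: 8371 features of group P4 had a mean of 0.93 and 6208 of group P6 a mean of 0.55. BRCA1+/- tumour 3 gained the 3782 features of group P14 (0.89). Losses in a single tumour, at the threshold used, included those of group P9 in BRCA1+/- tumour 5 (4754 features, -0.73) and of group P13 in wild-type tumour 6 (4076 features, -0.74). With the groups along the leading axes left out, the altered share by profile groups ran from 0.603% in wild-type tumour 4 to 19.1% in BRCA1+/- tumour 8. The order depended on the setting: with all groups counted BRCA1+/- tumour 1 was lowest (0.818%, wild-type tumour 4 at 3.71%), and with mode centring BRCA1+/- tumour 1 was highest (21.9%).

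In all, 40 groups holding 47.7% of the grouped features were lost in at least 1 tumour, and 24 groups with 32.8% were gained in at least 1. By profile groups the mean altered share was 8.59% ± 5.58 (SD, n = 16). By single features, the unit fixed beforehand, it was 19.1% ± 5.81, from 11.6% in BRCA1+/- tumour 3 to 31.1% in BRCA1+/- tumour 8, with 8.85% ± 4.24 gained and 10.3% ± 3.81 lost. The share by single features includes features pushed past the threshold by measurement noise.

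**Figure D1:**
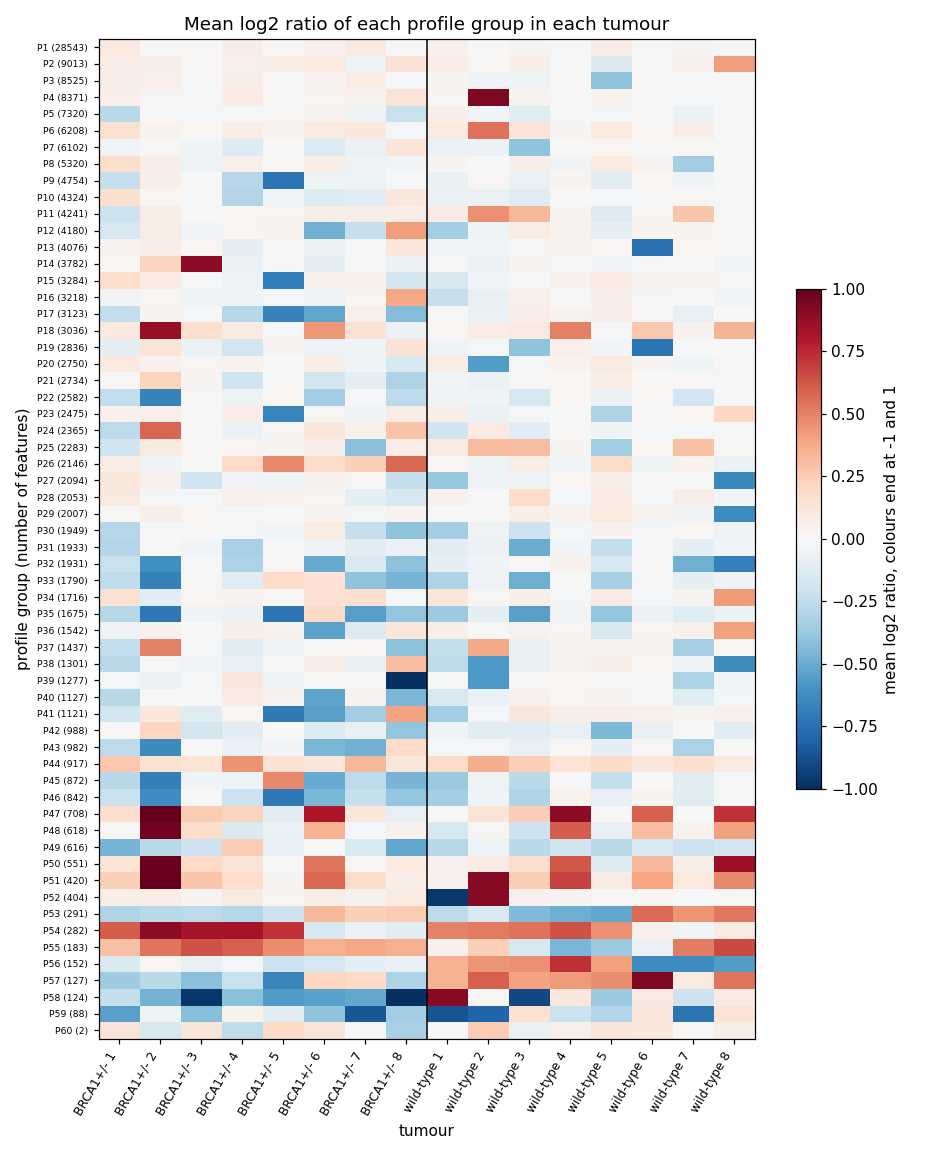
Mean log2 ratio (colour, ends at -1 and 1) of each of the 60 profile groups (vertical axis, number of features in brackets) in each of the 16 tumours (horizontal axis, BRCA1+/- left of the line). Group P4 reached 0.93 in wild-type tumour 2 and group P14 reached 0.89 in BRCA1+/- tumour 3.

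The second comparison asked which changes recurred over the tumours. At the threshold of 0.3, groups of at least 500 features were lost in 4 or more tumours. None was gained in as many once the 5 groups along the leading axes were left aside. Of those 5, P18 (3036 features) was gained in 4 tumours and P47 (708 features) in 5. At a threshold of 0.2, P44 (917 features) was gained in 5 tumours and P26 (2146 features) in 4. The axes carried 0.75 of the sum of squares of P44, short of the limit of 0.8, and 0.46 of that of P26. P44 lay above 0 in every tumour. Of the profile groups with at least 500 features, 7, with 9213 features or 5.37% of those grouped, were lost in at least 4 tumours. At a threshold of 0.2 there were 14 such groups, with 22154 features. Group P35 (1675 features) was lost in 7 tumours, at -0.72 in BRCA1+/- 2, -0.72 in BRCA1+/- 5, -0.55 in BRCA1+/- 7, -0.40 in BRCA1+/- 8, -0.36 in wild-type 1, -0.54 in wild-type 3 and -0.39 in wild-type 5. Groups P32 (1931 features), P33 (1790 features) and P46 (842 features) were each lost in 6 tumours. With the axis groups left out, the 5 groups gained in at least 4 tumours at 0.3 had 1035 features together and were all small. Several of them followed sex or genotype. Group P54 (282 features) lay between 0.46 and 0.90 in each of the 10 males and between -0.16 and 0.08 in the 6 females. Group P53 (291 features) was above 0 in all 6 females, 4 of them past the threshold, and below 0 in all 10 males. Group P56 (152 features) was gained in the 5 wild-type males (0.35 to 0.73) and lost in the 3 wild-type females (-0.63 to -0.56). No test of chance was made for the recurrence of groups.

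Over single features, 2443 were gained in at least 10 tumours and 1331 were lost in at least 11, where chance placement gave 0.0143 and 0.00388 features. Of these, 136 were gained and 34 lost in all 16 tumours. All arrays had the same dye orientation, so a fixed dye bias of a feature is not separable from a change present in most tumours.

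The third comparison asked whether tumours of BRCA1+/- rats carried more copy number change than those of wild-type rats. The altered share did not differ beyond the spread between tumours: it was 21.3% ± 6.91 (SD, n = 8) in BRCA1+/- and 16.9% ± 3.69 (SD, n = 8) in wild-type tumours, a difference of 4.38 percentage points (exact permutation p = 0.139, two-sided, adjusted p = 0.257 over 11 comparisons). The spread of the log2 ratios over the features of group P1 was also compared, after the data were seen. It was 0.1703 ± 0.0263 (SD, n = 8) in BRCA1+/- and 0.1496 ± 0.00689 (SD, n = 8) in wild-type tumours (exact permutation p = 0.0406, not adjusted). This spread is not noise alone, since pairs of arrays correlated across these features at a median r of 0.462. It was widest in BRCA1+/- 2 (0.219) and BRCA1+/- 8 (0.188), which also had the largest altered shares by single features (30.1% and 31.1%). BRCA1+/- 4 was next in spread (0.181), with a share of 17.5%. A wider spread takes more single features past the threshold, so the difference in altered share cannot be told apart from one in spread. The gained share was 9.56% ± 4.54 and 8.15% ± 4.09 (adjusted exact p = 0.643). The lost share was 11.8% ± 3.67 and 8.78% ± 3.54 (exact permutation p = 0.1203, adjusted p = 0.257). By profile groups at the same threshold the direction turned, with 7.89% ± 6.12 altered in BRCA1+/- and 9.29% ± 5.30 in wild-type tumours (difference -1.40, exact permutation p = 0.628), but the difference by profile groups was 3.50 at a threshold of 0.2, 0.992 at 0.5 and 2.71 with mode centring. Of the 60 groups, only the small group P57 (127 features) differed by genotype, at -0.23 ± 0.30 (SD, n = 8) in BRCA1+/- and 0.48 ± 0.24 (SD, n = 8) in wild-type tumours (exact permutation, adjusted p = 0.0280). It was above 0 in 8 of 8 wild-type and 2 of 8 BRCA1+/- tumours. The permutation treats single arrays as exchangeable, while 772 single features differed between the 4 genotype-and-sex sets (at most 20 in 100 random partitions). There are only 2 such sets per genotype, and no test over sets was made for P57. A chance difference between sets of arrays is therefore not excluded for it. Groups were compared by genotype with 60 components only. With no adjustment, 7 groups had p below 0.05.

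**Figure D2:**
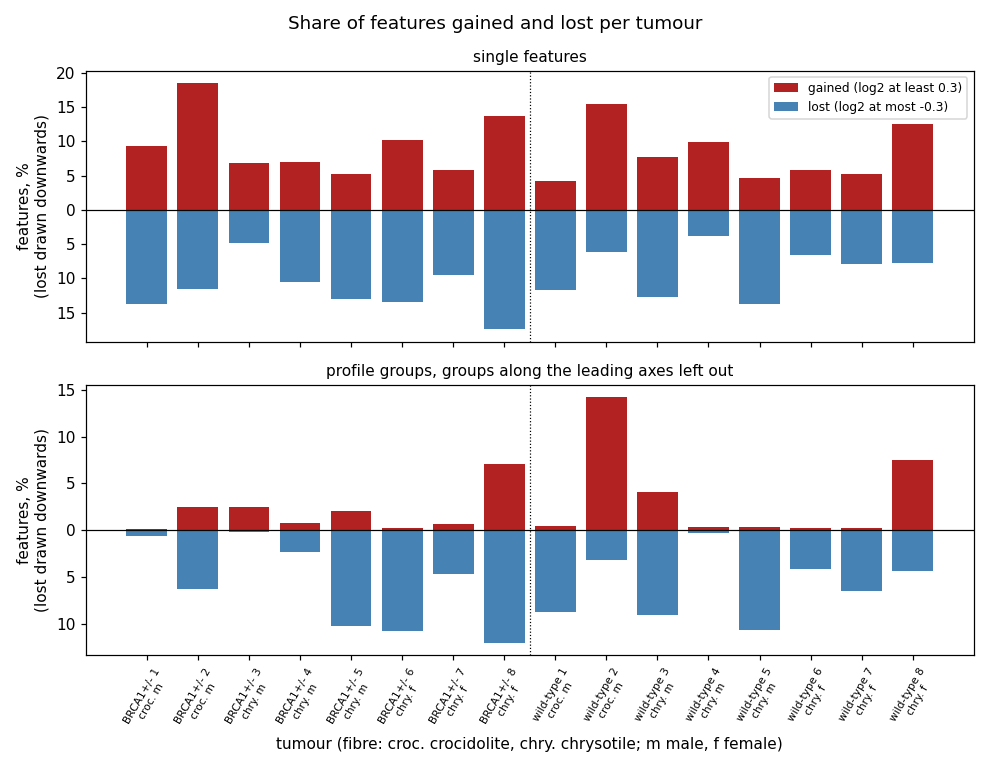
Percentage of features gained (upward bars) and lost (downward bars) in each tumour, by single features (upper panel) and by profile groups (lower panel), with BRCA1+/- tumours left of the dotted line. The altered share by single features ran from 11.6% to 31.1% and the genotypes overlapped.

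At single features, 56 of 174012 differed by genotype (limma, adjusted p below 0.05), 32 higher and 24 lower in BRCA1+/- tumours, with 13341 at an unadjusted p below 0.05. The median absolute difference of the 56 was 0.98 (log2). The 2 largest differences with lower ratios in BRCA1+/- tumours were at feature 54314 (-8.42, SE 1.40, limma adjusted p = 0.0406) and feature 2412 (-7.93, SE 1.23, limma adjusted p = 0.0223). In the opposite direction they were at feature 114009 (6.38, SE 1.06, limma adjusted p = 0.0406) and feature 31533 (4.00, SE 0.592, limma adjusted p = 0.0150). At feature 54314 the tumours had a mean of -2.35 ± 3.50 (SD, n = 8) in BRCA1+/- and 6.07 ± 2.81 (SD, n = 8) in wild-type. Neither mean was typical. Wild-type tumours lay at 1.41, 1.70 or between 7.19 and 8.44. BRCA1+/- tumours lay between -6.63 and -6.38 or between -0.44 and 1.02. Signal over background was not analysed, so the size of such large differences is uncertain. In a separate count, 44 features lay beyond 4 on every array of 1 genotype-and-sex set while the median of each other set lay within 1.5; single arrays of the other sets could lie further out. The count by genotype was 99 with fibre and sex in the model. A random block for genotype-and-sex sets, in which genotype is nested, had a negative estimated correlation (-0.0791), was not a stricter test and gave 332.

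The fourth comparison asked whether the fibre mattered, within males. The altered share was 22.6% ± 5.84 (SD, n = 4) in crocidolite and 16.7% ± 3.33 (SD, n = 6) in chrysotile tumours, a difference of 5.97 percentage points that did not pass the threshold (exact permutation p = 0.0667, adjusted p = 0.257). The gained share was 11.8% ± 6.38 against 6.87% ± 1.86 (exact permutation p = 0.114), and the lost share 10.8% ± 3.22 against 9.78% ± 4.38 (exact permutation p = 0.671). For profile groups the 210 relabellings allow no p below 0.00476, which would be 0.286 after adjustment for a group that reached it alone, and 6 groups at that p would have been needed to pass the adjusted threshold. Before adjustment 3 groups had an exact p below 0.05. No single feature differed (limma, 0 features, 5609 at an unadjusted p below 0.05; with array weights also 0). With genotype in the model 1 feature passed (limma adjusted p = 0.0340), and without BRCA1+/- tumour 1 there were 2 (smallest limma adjusted p = 0.00350). The share rested on single tumours: the difference was 8.23 without wild-type tumour 1 (exact permutation p = 0.0119) and 3.49 without BRCA1+/- tumour 2 (exact permutation p = 0.190). Centring on the mode gave 7.36 (exact permutation p = 0.0333). Profile groups gave 1.89 (exact permutation p = 0.643), but 7.88 at a threshold of 0.2 (exact permutation p = 0.0857) and 6.78 with mode centring (exact permutation p = 0.119).

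The fifth comparison set females against males among chrysotile tumours. The altered share was 19.3% ± 7.25 (SD, n = 6) in females and 16.7% ± 3.33 (SD, n = 6) in males (difference 2.60, exact permutation p = 0.461, adjusted p = 0.634). Profile groups P53 and P54 separated the sexes without overlap. Group P53 lay at 0.39 ± 0.14 (SD, n = 6) in females and -0.37 ± 0.13 (SD, n = 6) in males, and group P54 at -0.04 ± 0.09 and 0.67 ± 0.15. Both had the smallest p that 924 relabellings can give (exact permutation p = 0.00216, adjusted p = 0.0649 over 60 groups), and 3 groups at that p would have been needed to pass the adjusted threshold. In all, 6 groups had an unadjusted p below 0.05. At single features, 209 differed (limma, adjusted p below 0.05, 7958 unadjusted), 99 higher and 110 lower in females, with a median absolute difference of 1.04. Features of the sex chromosomes were not told apart from the others here.

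The genotype difference in the altered share was 7.81 percentage points among crocidolite males and -1.68 among chrysotile males, but these did not differ by test (interaction 9.50, exact permutation p = 0.133, adjusted p = 0.257). It was 8.16 among chrysotile females against -1.68 among chrysotile males (interaction 9.85, exact permutation p = 0.140, adjusted p = 0.257). By profile groups the interaction with fibre turned direction (-6.20, exact permutation p = 0.417), but not at a threshold of 0.2 (3.39, exact permutation p = 0.750) or with mode centring (3.73, exact permutation p = 0.617). At a threshold of 0.5 the interactions were 0.298 with fibre (exact permutation p = 0.900) and 0.683 with sex (exact permutation p = 0.820).

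Large changes of single tumours were sought as features at least 1.5 (log2) from the median of the other 15 tumours. Wild-type tumour 1 had 350 such gained features, 274 of them at least 3 above, with a median of 3.57, and wild-type tumour 3 had 30, with a median of 4.05. BRCA1+/- tumour 3 had 195 (median 1.67) and BRCA1+/- tumour 2 had 76. BRCA1+/- tumour 8 had the most lost features, 70 with a median of -1.79, followed by BRCA1+/- tumour 3 with 37. The mean count of gained features was 39.5 ± 67.3 (SD, n = 8) in BRCA1+/- and 54.4 ± 119.7 (SD, n = 8) in wild-type tumours (exact permutation p = 0.764). The mean count of lost features was 20.1 ± 22.7 (SD, n = 8) in BRCA1+/- tumours, 7.12 above that of wild-type tumours (exact permutation p = 0.504), while the medians ran the other way, 9.50 and 11.5.

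**Figure D3:**
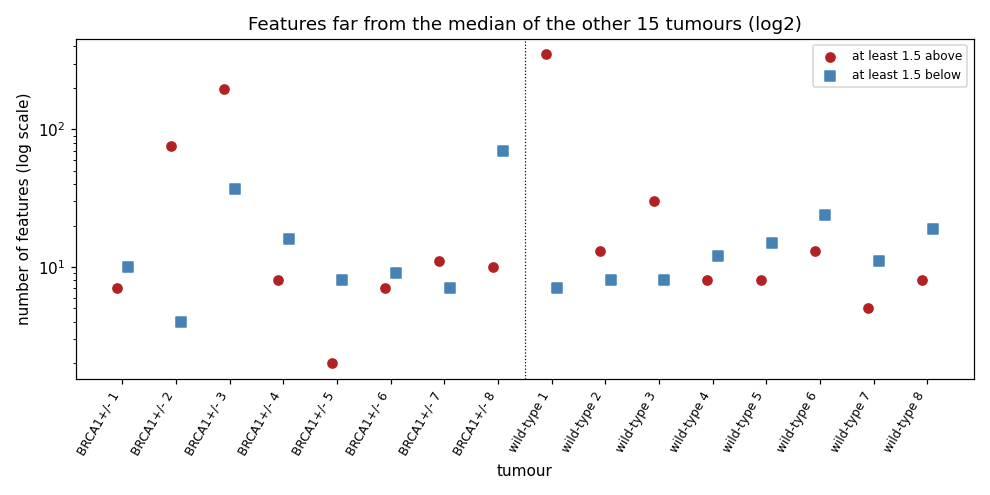
Number of features (log scale) at least 1.5 above (circles) or at least 1.5 below (squares) the median of the other 15 tumours, for each tumour. Wild-type tumour 1 stands highest with 350 gained features and BRCA1+/- tumour 8 has the most lost features, 70.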

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

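All tests in this part, and the measure behind them, were chosen after the data were seen. Over 6 measures in each genotype, 12 groups of 8 tumours, 2 tumours lay far from the others of their group. Chance flags about 1 in 20 groups only where the values are normally distributed. The flagged tumours came from skewed counts of features, so that rate does not apply to them. The measures also overlap, since the altered share contains the gained and the lost share.

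Wild-type tumour 1 had 350 features at least 1.5 (log2) above the median of the other tumours, and the gap to the next wild-type tumour was 0.928 of the whole range of the group. BRCA1+/- tumour 3 had 195 such features, with a gap of 0.617 of the range. No biological explanation was tested for either, since the features have no position here and neighbouring probes cannot be told from scattered ones.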

How the results depend on the processing

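All profile-group settings, the subtraction of feature medians and the random block were chosen after the data were seen; unless stated, the cause of a change was not tested. Not run for want of positions and gene names: the segmentation alternatives, mean over probes, at least 3 probes per gene, segment means, and all chromosome and gene list settings. The number of arrays limits every comparison, and signal over background was not analysed here. The mean altered share of 19.1% became 33.8% and 7.55% at thresholds of 0.2 and 0.5. By profile groups it was 9.47%, and with the axis groups left out 8.59%, 13.02% (threshold 0.2), 3.42% (0.5), 8.23% (40 components), 9.26% (80), 10.4% (mode) and 8.07% (no centring).

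The genotype difference of 4.38 kept its direction and stayed short of the threshold in 8 of 13 alternatives. It reversed by profile groups (-1.60), with the axis groups left out (-1.40), and then with 40 (-0.966) or 80 components (-0.287) or no centring (-0.623), but not at threshold 0.2 (3.50) or 0.5 (0.992) or with mode centring (2.71). The fibre difference of 5.97 kept its direction in all 16 alternatives. By profile groups it was 2.21, and with the axis groups left out 1.89, 1.35 (40 components), 2.05 (80), 1.93 (no centring), 2.88 (threshold 0.5), 7.88 (0.2) and 6.78 (mode). It passed the threshold with mode centring (7.36) and without wild-type 1 (leaving out single crocidolite tumours, 3.49 to 8.23). No chrysotile tumour was left out in the fibre comparisons. The sex difference kept its direction and side in all 12. The interaction with fibre reversed by profile groups (-3.74), and with the axis groups left out (-6.20), at threshold 0.5 (-5.63), 40 (-2.33) or 80 components (-6.04) or no centring (-4.46), but not at threshold 0.2 (3.39) or with mode centring (3.73), and ran from 5.97 to 13.03 when single tumours were left out. The interaction with sex reversed in 1 of 24, by profile groups at threshold 0.5 (-3.87), and ran from 5.97 to 13.9 without single tumours. At threshold 0.5 on single features the interactions shrank to 0.298 (fibre) and 0.683 (sex).

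Recurrent features went from 3774 to 0 after each feature's median was subtracted, an outcome fixed by that step. At most 8 tumours can then lie on either side, while 9 were needed for a gain and 10 for a loss. Features by genotype went from 56 to 99 with fibre and sex in the model (52 shared) and to 332 with the random block, in which genotype is nested and whose estimated correlation was negative (-0.0791). Features by fibre went from 0 to 1 with genotype in the model and to 2 without BRCA1+/- 1, with 0 to 2 over single crocidolite tumours left out. Features by sex (209) stayed within 1.5 times in all 4 alternatives.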

Other observations

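In this part only the comparisons of the genotype and sex counts with other splits of the arrays were planned. The fibre splits, the comparisons of genotype-and-sex sets and the tests on reference DNA, tumour-cell changes, shared trends, deep losses, loss levels and recurrent groups were chosen after the results were seen. The criterion for a shared trend was revised once, because its first form could not have failed, and the revised form was void too. The tests on tumour-cell changes and on a single level of gain also proved void.

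Features with deep loss in several tumours were sought, so their recurrence follows from the search, and no count expected by chance was made. The 294 taken lay at or below -1 in at least 3 tumours and near or above 0 in at least 5. By choice, none lay far above 0 in any tumour. The largest correlated cluster had 28, with mean log2 ratios of -1.78 in BRCA1+/- 8, -1.42 in BRCA1+/- 3, -1.17 in wild-type 3 and -1.02 in BRCA1+/- 6. It lay at -0.80 in BRCA1+/- 7, -0.62 in BRCA1+/- 5, -0.58 in BRCA1+/- 2, -0.41 in BRCA1+/- 4 and -0.24 in BRCA1+/- 1. In the other wild-type tumours it lay at -0.37 (wild-type 5), -0.32 (wild-type 1) and -0.23 (wild-type 7), and between 0.02 and 0.10 in wild-type 2, 4, 6 and 8. The second cluster, of 23 features, was lowest in 4 males, at -2.61 in BRCA1+/- 4, -2.54 in wild-type 3, -2.51 in wild-type 1 and -2.43 in BRCA1+/- 3. The other males ran from -1.06 in wild-type 4 to 0.05 in BRCA1+/- 5, and the females from -0.02 to 0.41. The third, of 17, lay at or below -1.17 in the males BRCA1+/- 1 to 4, wild-type 1 and wild-type 3. The female wild-type 6 (-0.79) was next, below the males wild-type 5 (-0.61), BRCA1+/- 5 (-0.49), wild-type 2 (-0.36) and wild-type 4 (0.04), and the other females ran from 0.07 to 0.34. No genotype difference was tested for these clusters. The typical level of groups of at least 500 features at or below -0.2, a limit that leaves out shallower losses, was -0.45 ± 0.17 (SD, n = 7) in BRCA1+/- and -0.49 ± 0.16 (SD, n = 7) in wild-type tumours (exact permutation p = 0.636). It ran from -0.26 in BRCA1+/- 1 to -0.74 in wild-type 6, with BRCA1+/- 3 and wild-type 4 left out for having at most 1 such group. BRCA1+/- 1 had 0.653% of features lost by profile groups with median centring and 21.7% with mode centring.

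The 7 recurrently lost groups of at least 500 features were lost 24 times of 56 in BRCA1+/- and 13 times of 56 in wild-type tumours, a mean of 3.00 ± 2.39 and 1.63 ± 1.77 groups per tumour (exact permutation p = 0.252, n = 8 each). This was 1 of 16 settings computed, over the group size, the number of tumours and the threshold. BRCA1+/- tumours had more in all 16, with exact permutation p from 0.0216 to 0.489. In 4 settings p was below 0.05, all with the threshold of 0.2 and with small groups included, and after adjustment over the 16 the smallest was 0.173.

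For the 56 features that differed by genotype, 1 of 100 splits of the arrays into 8 and 8, the real one, gave as many, and the highest other split gave 42. Chance differences between sets of arrays are not excluded by these splits. The splits treat single arrays as exchangeable, while 772 features differed between the 4 genotype-and-sex sets (at most 20 in 100 random partitions, differences by genotype and by sex included). Splitting the arrays across the sets, females of each genotype with males of the other, called 37 features. Of the 99 other splits, 1 reached that count. There are only 2 sets per genotype, and no test over sets was made. Changes of the tumour cells stay open. They would scale with the depth of losses in the same tumours, and the median correlation over the 56 features was 0.0678 (quartiles -0.198 and 0.271), but this decides nothing, because the features were called for a small spread within each genotype and no known copy number change shows what correlation to expect. Reference DNA shared within each genotype and sex is a candidate source. In 44 features every array of 1 such set lay beyond 4 while the median of each other set lay within 1.5. Random partitions, 100 in all, gave at most 18. Single arrays of other sets lay further out in many of the 44. Several of the 44 repeated the same pattern over the arrays, so they are not independent. That such DNA accounts for the 56 features themselves was not tested, and inherited differences between the genotypes stay open.

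For sex, 1 of 100 splits of the 12 chrysotile arrays, the real one, gave as many as 209 features, and the highest other split gave 41. Chance differences between sets of arrays are again not excluded by these splits. These arrays also fall into only 2 sets per sex, and no test over sets was made. The split across the sets called 22, a count that 2 of the 99 other splits reached. For fibre no feature was called, so all 100 splits gave as many by construction (the highest 20), and the splits decide nothing.

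The 5 groups along the leading axes (5333 features) were all above 0.3 in BRCA1+/- 2, wild-type 4, BRCA1+/- 6 and wild-type 8, and between 0.27 and 0.60 in wild-type 6. In the largest group, which lay near 0, BRCA1+/- 2 and wild-type 4 correlated at 0.730 across 28543 features, 0.267 above the median pair of arrays (0.462) and ranked 3 of 120 pairs. The spread of the 5 groups in BRCA1+/- 2 was 1.476 times that of the largest group (0.323 against 0.219), which decides nothing about a gain with a single level, because the groups were picked along the axes of the spread within groups and BRCA1+/- 2 loads these most. The correlation decides nothing about a trend shared by all features, because the axes that define these groups come from the spread within groups and already load this pair together. Such a trend and gains at 1 or several levels stay open.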
